A study of Rattus norvegicus with 40 samples.

How the data were processed

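Gene expression was measured in rat liver with 1-colour Agilent microarrays, 40 arrays in 8 groups of 5. Rats received either the CDAA diet, short for choline-deficient and defined in L-amino acids, which is used to bring about fatty liver disease in rodents, or a diet labelled normal, whose composition is not stated. Liver was taken after 1, 2, 4 or 9 weeks. The series text says that each group contains 5 different samples. Strain, sex and age are not given in the labels.

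Per the labels, total RNA from frozen liver was labelled with Cy3. The scanner tables give spot intensity per the file headers, written by Agilent Feature Extraction 11.0.1.1, whereas the submitters' processing notes name version 12.0. The column used was the processed signal, a linear intensity that is background-subtracted and detrended within 1 array and not normalized between arrays. The authors also deposited a table of log2 values for 19568 probes, with its normalization and filter unstated. Set against log2 of the processed signal, its columns correlated at r = 0.992 to 0.998 across probes with slopes of 0.872 to 0.922. Its column medians ran from 9.66 to 9.75 on the CDAA diet and from 9.84 to 9.92 on the normal diet, and 19565 of its probes were well above background on all 40 arrays. It was used as an alternative only.

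Each array held 58717 non-control spots of 45598 different probes. The value of a spot was log2 of its processed signal minus the 75th percentile of its array over the non-control spots. Spots marked as non-uniform or as population outliers were left out, repeated spots of a probe were averaged, and 0 spots were saturated. Probes were kept when they were well above background on at least 4 of 5 arrays of at least 1 group, which left 27129. Genes were named by matching the accession of each probe, without its version, to the rat gene table of assembly GRCr8, used for names only and not for positions. Of the 45598 probes, 21109 matched and 24489 did not. Where several kept probes had 1 symbol, the probe with the highest mean over all 40 arrays stood for the gene. The 23127 features tested were 12022 genes with a symbol and 11105 unnamed features under their accession, all called genes here. A probe can also bind related transcripts, which was not tested, so values of members of the Cyp2, Cyp3a, Gst, Sult and haemoglobin families may include paralogs.

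One linear model with a mean for each of the 8 groups was fitted across all 40 arrays in limma 3.58.1 (R 4.3.3, with version 1.17.8 of the package data.table), with 32 residual degrees of freedom and empirical Bayes variances. Contrasts were CDAA minus normal diet at each week, the difference of that contrast between 9 weeks and 1 week, a moderated F test of the diet-by-week interaction, and 9 weeks minus 1 week on each diet. All tests were two-sided, and p values were adjusted by Benjamini-Hochberg over the genes of a contrast. Adjusted p and standard errors (SE) printed for genes come from this limma fit, and a gene was called at an adjusted p under 0.05. Measures of whole arrays were compared by exact permutation of the 10 arrays of a week, for which the smallest two-sided p is 0.00794. On data simulated with 5 arrays per group, 30% of genes changed 1.25-fold, 78% of those changed 2-fold and 96% of those changed 4-fold were called, and 0 of 22927 unchanged genes were called at 1 week. Only 200 genes were changed there, noise was independent between genes, and arrays did not differ in brightness. The measured arrays differ in these points, so the percentages need not hold for them.

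The 41 gene lists tested, with at least 5 measured members each, were fixed before the data were examined, as were the comparisons, tests, thresholds and most alternatives. They cover liver metabolism, fibrosis, cell type markers, inflammation, growth, stress responses and neighbouring tissues. Lists were tested with limma's camera, which compares the members with all other genes, at its preset correlation of 0.01, with adjustment over the lists of a contrast. Camera was repeated with the correlation estimated from the data, whose median over the lists was 0.185. In fry, run beside it, a small p shows that members move on balance in 1 direction, without a comparison with other genes. Members called within a list are counted over all genes tested and also adjusted over the list alone. A list's score on an array is the mean of its members after each is centred over the 40 arrays.

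Genes are named by a rule. It takes, at each week, the largest changes in either direction among genes with a symbol other than a LOC number, well above background on at least 4 of 5 arrays of both groups and without overlap of the 5 CDAA and 5 normal-diet values. It adds, for each list that passes, called members with the smallest p in the list's direction and 1 against it, and the largest changes of both comparisons over time. A set of 21 indicator genes is named at every week whatever its result, except 1 that is not reported here. Where a gene was well above background on no array of 1 group, the fold is a lower bound, written as at least N-fold. The bound sets the brighter group's mean against the dimmer group's mean of, per array, the gene's own signal or the lowest signal among probes well above background, whichever is higher.

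Alternatives changed 1 choice at a time, apart from 2. Normexp also replaced the processed signal by the median signal, and the deposited table changed the normalization, the filter and the probes together, with 16746 of its probes used. The alternatives were quantile normalization, the deposited table, normexp background correction with offset 50, no filter on dim probes or a filter for probes above background on all 40 arrays, and the mean of all probes of a gene. Others were a trended and robust variance, array weights, fitting only the groups compared, stricter thresholds, the estimated correlation, and the slide, scan day or replicate number as a block. Each array was also left out in turn. The planned normexp correction on the mean signal was run on the median signal, since the mean is not among the columns. Chosen after seeing the data were scaling each array to its 7 E1A spike-in probes with a mean log2 signal above 6, centring on the probes above background on all 40 arrays, and leaving out the 8 arrays of slide 2. By the design of the kit a fixed amount of spike-in RNA goes to each labelling reaction, so this scale keeps differences in total signal that the 75th percentile removes. No array was left out of the results given first.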

Results

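Liver from rats fed the CDAA diet was compared with liver from rats on the normal diet after 1, 2, 4 and 9 weeks, with 5 arrays for each diet and week. The series sets out to follow gene expression in a diet-made model of non-alcoholic fatty liver disease. Between 47.9% and 61.3% of the 45598 probes were well above background on an array. Arrays of 1 group correlated at r = 0.985 to 0.996 across genes. The first principal component held 67.3% of the variance. The 40 arrays sat on 5 slides. Replicates 1 to 4 of both diets of a week shared a slide, 1 slide for each week. The fifth replicates of all 8 groups shared another. Replicates 1 to 4 of weeks 1 and 2 were scanned on 1 day and all other arrays on another. Week and scan day therefore lie largely together. Every array of that other day had the scanner quality result Evaluate in place of InRange, as did replicate 4 of the CDAA diet at 2 weeks. On every slide the CDAA arrays were in the first row and the normal-diet arrays in the second, so position within a slide and diet cannot be told apart.

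CDAA arrays were brighter than normal-diet arrays at every week. The 75th percentile of signal was 3230 ± 189 (SD, n = 5) on the CDAA diet and 1750 ± 154 on the normal diet at 1 week, and 3856 ± 526 against 1496 ± 126 at 9 weeks. No array of either diet overlapped the other at any week (exact permutation p = 0.00794 at each week, the smallest possible, and adjusted p = 0.00794). Spike-in probes did not share the difference: CDAA minus normal diet, their mean log2 signal differed by -0.02, -0.17, -0.08 and -0.20 at the 4 weeks (exact permutation p = 0.786, 0.0159, 0.246 and 0.0556, adjusted p = 0.786, 0.0635, 0.328 and 0.111). The choice of scale therefore moves every gene. Relative to the 75th percentile the median log2 fold change of all genes was -0.15, -0.19, -0.26 and -0.33 at weeks 1, 2, 4 and 9, and relative to the spike-in probes it was 0.76, 0.87, 1.04 and 1.23. Spike-in scaling adds 0.91, 1.06, 1.30 and 1.56 to every log2 fold change of the respective week. Higher and lower below mean relative to the 75th percentile of each array unless spike-in scaling is named. A fold change under either scale orders the genes in the same way within a week.

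**Figure D1:**
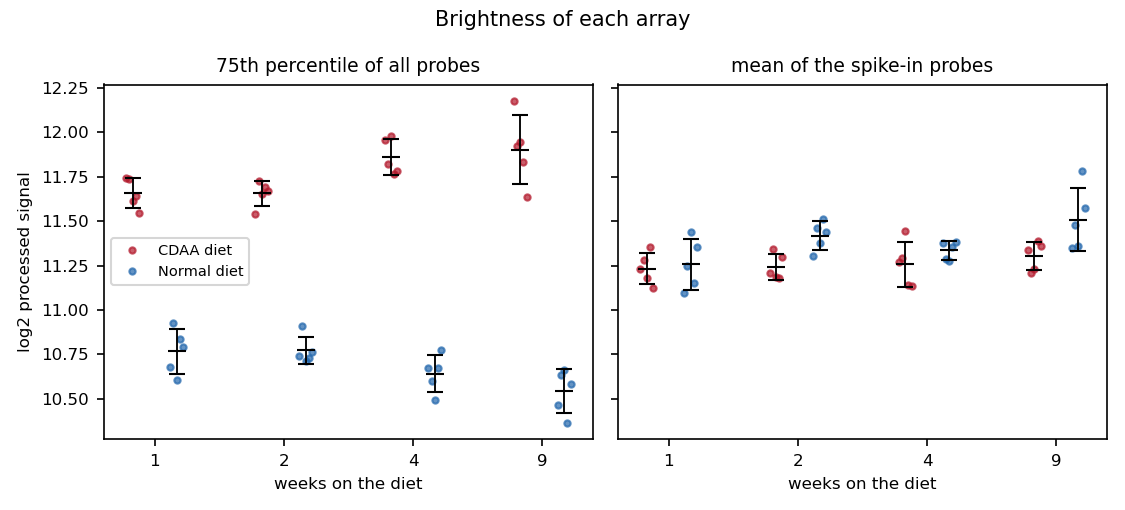
Each point is 1 array, plotted by weeks on the diet, with the 75th percentile of log2 signal on the left and the mean log2 signal of the spike-in probes on the right, and bars give the mean and SD of 5 arrays. CDAA arrays lie at 11.54 to 12.18 on the left and normal-diet arrays at 10.37 to 10.93, while on the right both diets lie between 11.09 and 11.78.

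After 1 week on the diet, genes of recruited macrophages, cell injury and the stress hormone FGF21 were already far higher, and genes of hepatocyte metabolism were lower. Trem2, a receptor of lipid-handling macrophages, was well above background on 5 CDAA arrays and 0 normal-diet arrays and at least 133-fold higher (adjusted p = 3.5e-28). Gpnmb, of the same cells, had a log2 fold change of 4.26 (SE 0.10, adjusted p = 5.7e-27), and Ccl2, a chemokine that draws monocytes, was at least 63.8-fold higher. Among genes well above background on both diets Fgf21, a hormone secreted by stressed liver, came first with a log2 fold change of 5.88 (SE 0.37, adjusted p = 7.9e-16), followed by Gstm3 at 5.36, Fabp4 at 5.35, Atf3 at 5.31 and Mogat3, an enzyme of triglyceride synthesis, at 5.14. At the other end stood Stac3 at -9.14, Inmt at -7.27, Sds at -6.36, Cyp3a9 at -4.81 and Oat at -4.76. In all, 15429 of 23127 genes were called, 5510 higher and 9919 lower, of which 1960 and 2168 changed at least 2-fold. Spike-in scaling turns the balance, with 16974 higher and 1145 lower. All 5510 were also called higher with it, whereas of the lower genes 1145 were called lower on both scales and 4817 were lower on the first and higher on the second. The 5 CDAA and 5 normal-diet values did not overlap for 50.7% of genes, where chance gives 0.794%. Among 78 called values of named genes checked at 1 week, all 5 CDAA arrays lay beyond all 5 normal-diet arrays for 76, the exceptions being Fasn with 4 and Krt19 with 2. At this and the later weeks such lack of overlap was a condition for naming the largest changes. For those genes the counts therefore do not test it.

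Lists of immune and scar-forming cells were higher at 1 week. Of 19 measured markers of recruited and lipid-associated macrophages 16 were called higher and 1, Cx3cr1 at -1.46, lower, with a median log2 fold change of 2.42, also with bounded members at their bound (camera adjusted p = 5.8e-11, and 0.016 with an estimated correlation). Cytoskeleton and epithelial injury genes had 20 of 26 higher and 2 lower, with a median of 1.09 (adjusted p = 5.8e-11, and 0.035 with an estimated correlation). Anxa2 and Anxa5, annexins that are members there, had log2 fold changes of 2.58 and 2.30. These 2 were the lists whose call held with the estimated correlation at 1 week. Extracellular matrix had 32 of 39 members higher and 2 lower, with a median of 1.04, or 0.85 with 5 members at their bound. Examples were Timp1, an inhibitor of matrix breakdown, at 2.54 (SE 0.09), Mmp9 at least 5.42-fold higher, and Col1a1, the main fibrillar collagen, at 1.54 (SE 0.17). Stellate cell and myofibroblast markers had 15 of 27 higher and 3 lower (median 0.37), with Vim at 1.59 and Acta2, the marker of contractile scar-forming cells, at 0.38 (SE 0.12, adjusted p = 0.0078). Without replicate 2 of the CDAA diet Acta2 was at 0.25 and no longer called (adjusted p = 0.057), nor was it with normexp (0.014). Pan-macrophage markers had 19 of 22 higher (median 0.91), Cd68 among them at 1.08. T cell and natural killer markers had 16 of 22 higher (median 1.30, or 1.12 with bounds), with Zap70 at 2.21. Neutrophil markers had 7 of 9 (median 0.98), with Ncf1 at 1.38. Antigen presentation genes had 11 of 13 (median 1.08), with Cd83 at 2.93. Endothelial markers had 15 of 21 (median 0.51), with Oit3 at 1.41. Chemokines and adhesion molecules had 25 of 34 (median 1.13, or 1.02 with bounds), with Ccl7 at least 11.6-fold higher. Interferon-stimulated genes had 17 of 28 higher and 5 lower (median 0.94), with Isg15 at 2.60 and Isg20 at 2.09. For these 9 lists camera gave adjusted p of 7.3e-11 to 0.0014, and 0.071 to 0.23 with an estimated correlation.

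Smaller shifts at 1 week passed camera as well. Hepatic preneoplasia and oncofetal markers had 6 of 15 higher and 3 lower (median 0.52), with Gstp1, the placental glutathione transferase of altered foci, at 0.73 (SE 0.37, adjusted p = 0.081). Cell cycle genes had 14 of 38 higher and 3 lower (median 0.33), with Mki67 at 0.69. On single arrays their mean score lay above the mean of the normal diet on 4 of 5 CDAA arrays. Of 21 p53 targets 12 were higher and 4 lower (median 0.55), with Btg2 at 1.95 and Cdkn1a, the growth arrest gene, at -0.42 (0.49 with spike-in scaling). Apoptosis genes had 11 of 23 higher and 7 lower (median 0.27). The list of endoplasmic reticulum stress and amino acid response had 15 of 32 higher and 8 lower, with a median of 0.01 beside a mean of 0.75. Asns, which makes asparagine, was at 3.48 and Psat1, of serine synthesis, at 2.41, whereas Edem1, of protein quality control, was at -1.52. Adjusted p for these 5 lists was 0.00026 to 0.016, and 0.056 to 0.48 with an estimated correlation. Cholangiocyte markers did not pass (median 0.25, adjusted p = 0.051), with Krt19 at 0.50 (SE 0.22, adjusted p = 0.041). Without any 1 of 5 arrays the list passed, and without any 1 of 6 arrays Krt19 was no longer called.

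Metabolic lists were lower at 1 week. In choline, methionine and one-carbon metabolism 19 of 25 members were lower and 3 higher (median -1.36, and -0.45 with spike-in scaling). Gnmt, which disposes of excess methyl groups, was at -3.66 and Pipox at -1.96, Bhmt, which remakes methionine from betaine, at -1.61, and Pemt, which makes phosphatidylcholine from phosphatidylethanolamine, at -0.92 (-0.01 with spike-in scaling). Mat2a went against the list at 2.37. Urea cycle and amino acid catabolism had 27 of 29 lower (median -1.45, spike-in -0.54), with Prodh at -4.16. Cytochrome P450 and conjugating enzymes had 36 of 38 lower (median -1.27, spike-in -0.36), with Cyp2d4 at -2.09 and Cyp2e1 at -1.10. Bile acid genes had 17 of 22 lower and 4 higher (median -1.07, spike-in -0.16), with Slc27a5 at -2.68, Baat at -1.67, Cyp7a1, which starts bile acid synthesis, at -3.93 (SE 0.47) and Cyp7b1 at 1.40. Lipoprotein genes had 23 of 24 lower (median -1.0, spike-in -0.09), with Pon1 at -1.97. Hepatocyte secretory genes had 30 of 30 lower (median -1.03, spike-in -0.12), with Fetub at -1.90 and Alb, serum albumin, at -0.80 (0.11 with spike-in scaling). Growth hormone axis and male-biased genes had 17 of 20 lower (median -0.98, spike-in -0.07), with Igf1 at -1.84. Red blood cell and platelet markers had 9 of 9 lower (median -2.28, spike-in -1.37), with Slc4a1 at -2.90 and Hbb-b1 at -2.28. Other lists lay below 0 on the first scale and above 0 with spike-in scaling. These were lipogenesis (median -0.84 and 0.07, 19 of 21 lower), with Dgat2 at -1.66, Fasn at -0.99 and Scd at -1.20, cholesterol synthesis (-0.43 and 0.48, 16 of 25 lower, a call lost without replicate 2 of the CDAA diet at -0.34, adjusted p = 0.059), with Tm7sf2 at -3.61 and Hmgcs1 at 0.68, and gluconeogenesis (-0.86 and 0.05, 14 of 17). Oxidative phosphorylation (-0.60 and 0.31, 43 of 46 lower, Ndufa6 at -0.97), acute-phase proteins (-0.78 and 0.13, 14 of 21 lower and 5 higher, Itih3 at -1.17 and A2m at 2.92, with the camera direction turned by quantile normalization and in the deposited table) and clock genes (-0.55 and 0.36, 10 of 14, Nr1d1 at -2.52) did the same. Adjusted p of these 14 lists was 2.0e-12 to 0.038, and 0.071 to 0.58 with an estimated correlation. With spike-in scaling 26 of the 30 lists that passed kept a call in the same direction. Camera compares members with all other genes, and spike-in scaling adds 1 amount to every gene. This count therefore does not show that the direction of a list holds on both scales.

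The remaining 10 lists did not pass at 1 week (adjusted p = 0.095 to 1.0). Fatty acid oxidation had 11 of 32 members higher and 10 lower, with a median of 0.06 and a mean of 0.56. Cpt1a, the entry step of mitochondrial oxidation, was at 0.60. Lipid droplet proteins had a median of 0.06 and a mean of -0.14, with Plin2, which coats lipid droplets, at 1.1. Medians were 0.10 for Kupffer cell markers, 0.05 for B cells, 0.04 for mast cells, -0.03 for glycolysis (mean 0.26), -0.38 for NRF2 targets, -0.19 for lysosome genes, -0.23 for pancreas and 0.12 for adipose and muscle markers. With spike-in scaling the medians of these 10 lists were all above 0, from 0.53 to 1.03. The last 2 lists are a check for neighbouring tissue. Counted with p adjusted over the list alone, members called were the same or differed by at most 3 in every list at 1 week, the largest difference being 11 in place of 14 for higher cell cycle genes.

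At 2 weeks the same kinds of genes differed, and the list of bile duct cell markers, which fell just short at 1 week, passed. Among genes well above background on both diets Mogat3 had the highest log2 fold change at 6.83 (SE 0.27, adjusted p = 3.8e-21), then Fgf21 at 5.81, Adm2 at 5.63, Atf3 at 5.46 and Fabp4 at 5.46. Stac3 at -10.84, Aox3 at -6.11, Cyp3a9 at -5.89 and the sulfotransferase Sult2a1 at -5.42 were lowest among these. Cholangiocyte markers had 13 of 20 higher and 1 lower (median 1.11, camera adjusted p = 1.6e-05, and 0.083 with an estimated correlation), with Cldn7 at 2.59, Cftr, a chloride channel of bile ducts, at 2.29 (0.45 and not called with the mean of its probes) and Krt19 at 1.1 (SE 0.22, adjusted p = 3.2e-05). Recruited macrophage markers had 15 of 19 higher (median 2.30, or 2.11 with bounds), with Trem2 at least 153-fold higher and Gpnmb at 4.16. Cytoskeleton genes had 24 of 26 higher (median 0.95), with Anxa5 at 3.33. The last 2 were the lists that held with the estimated correlation, each at adjusted p = 0.014. Matrix genes (31 of 39 higher, median 1.03, Timp1 at 2.75, Col1a1 at 1.36), stellate cell markers (14 of 27, median 0.47, Acta2 at 0.36, or -0.022 and not called with normexp) and chemokines (27 of 34, median 1.17, Cxcl16 at 2.42) were higher with adjusted p of 0.00025 or less, and 0.083 to 0.13 with an estimated correlation. Ccl2 was at 5.07 and Cd68 at 1.32. Mast cell markers passed at 2 weeks (median 0.32, or 0.00 with bounds, adjusted p = 0.047, and 0.10 with an estimated correlation), with Hdc, which makes histamine, at 2.68. Without any 1 of 5 arrays that call was lost. Cell cycle genes had 28 of 38 higher (median 0.60, adjusted p = 1.7e-05, and 0.32 with an estimated correlation), with Ccnd1 at 1.61, Mki67 at 1.27 and Mcm3 at 1.09 (0.11 and not called with the mean of its probes).

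Metabolic lists at 2 weeks repeated the directions of 1 week. Among choline and methionine genes 20 of 25 were lower (median -1.20, spike-in -0.14), with Gnmt at -3.51, Bhmt at -1.70, Pemt at -0.88 (0.18 with spike-in scaling) and Mat2a at 2.05. Male-biased genes had 18 of 20 lower (median -1.11, spike-in -0.05), with Cyp2a2 at -3.15, and red blood cell markers 8 of 9 (median -1.89, spike-in -0.83), with Slc4a1 at -2.57. P450 enzymes had 35 of 38 lower (median -1.60, spike-in -0.54). The adjusted p of these 4 lists was 0.0052 or less, and 0.083 to 0.29 with an estimated correlation. Cholesterol synthesis passed narrowly (median -0.54, camera adjusted p = 0.049). That call was lost without replicate 2, 3, 4 or 5 of the CDAA diet or replicate 1, 2 or 4 of the normal diet. Fasn was at -0.78 (0.27 with spike-in scaling), Scd at -1.10, Cyp7a1 at -1.79, Cpt1a at 0.48, Plin2 at 1.12 and Cdkn1a at -0.59 (0.47 with spike-in scaling). Cyp2e1 was at -0.68 and Alb at -0.78, and both were called higher with spike-in scaling, at 0.38 and 0.28. Gstp1 was at 0.86 (SE 0.37, adjusted p = 0.036), a call that was lost without any 1 of 8 arrays (0.82 to 0.88). In total 16143 genes were called, 5752 higher and 10391 lower, with 2220 and 2441 at least 2-fold. With spike-in scaling 18142 were higher and 1100 lower, and 6105 were lower on the first scale and higher on the second. Of 42 called values of named genes checked at 2 weeks, 38 had all 5 CDAA arrays beyond all normal-diet arrays, and 55.6% of all genes did not overlap. The lists that passed numbered 30, 17 higher and 13 lower. They differ from those of 1 week in that cholangiocyte and mast cell markers passed, while the amino acid response list (median -0.22, mean 0.63, adjusted p = 0.18) and clock genes (median -0.38, adjusted p = 0.36) did not. The difference in these lists between 1 and 2 weeks was not tested.

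At 4 weeks, among genes well above background on both diets, H19, a fetal growth transcript, led the increases with a log2 fold change of 7.78 (SE 0.41, adjusted p = 3.2e-18), followed by Fgf21 at 6.50, Abcb1b, a drug exporter, at 6.29, Phgdh, the first enzyme of serine synthesis, at 6.20 and Gpx2 at 5.42. Stac3 at -11.86, Cyp3a9 at -6.71, Sult2a1 at -6.33 and Sez6 at -5.77 were lowest among these. Cholangiocyte markers had 17 of 20 higher and 2 lower (median 1.70, adjusted p = 9.9e-08, and 0.045 with an estimated correlation), with Cftr at 3.67, Krt19 at 2.29 and Epcam at 1.62. Matrix genes had 32 of 39 higher (median 1.59, or 1.55 with bounds, adjusted p = 6.2e-14, and 0.048 with an estimated correlation), with Timp1 at 3.23, Loxl1, which cross-links elastin and collagen, at 2.78 and Col1a1 at 2.76. Recruited macrophage markers (15 of 19, median 2.09, or 1.90 with bounds) and cytoskeleton genes (23 of 26, median 1.54) held at adjusted p of 0.020 and 0.018 with an estimated correlation, which makes 4 lists. Trem2 was at least 180-fold higher, Ccl2 at least 34.1-fold, Anxa5 at 3.92 and Cd68 at 1.1. Cell cycle genes had 34 of 38 higher (median 1.64, adjusted p = 4.1e-13, and 0.12 with an estimated correlation), with Mki67 at 2.49, Mcm3 at 1.82 and Tyms at 1.28. Stellate cell markers had 22 of 27 higher (median 0.90, or 0.82 with bounds, adjusted p = 2.0e-07, and 0.069 with an estimated correlation), with Acta2 at 0.69 (0.12 and not called with normexp). T cell markers passed with a median of 0.29, or 0.15 with bounds (adjusted p = 0.022, and 0.41 with an estimated correlation), with 0 of 5 CDAA arrays beyond all normal-diet arrays in their mean score. Interferon-stimulated genes did not pass at 4 weeks, with 10 of 28 higher, 13 lower and a median of -0.28 (1.02 with spike-in scaling, camera direction up, adjusted p = 0.83).

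Lower lists at 4 weeks included male-biased genes (18 of 20, median -1.60, spike-in -0.30, Cyp2c11 at -4.30), choline and methionine genes (19 of 25, median -1.45, spike-in -0.15, Gnmt at -3.78, Bhmt at -2.33, Mat2a at 2.18), clock genes (13 of 14, median -0.96, spike-in 0.34, Nr1d1 at -2.60) and red blood cell markers (8 of 9, median -2.22, spike-in -0.92, Slc4a1 at -3.32). Adjusted p was 4.9e-05 to 0.027, and 0.084 to 0.36 with an estimated correlation. Cholesterol synthesis had 25 of 25 members lower (median -1.17, spike-in 0.12, adjusted p = 2.0e-05, and 0.28 with an estimated correlation). Fasn was at -2.27, Scd at -1.70, Cyp7a1 at -3.40, Pemt at -1.29 (0.01 with spike-in scaling), Cpt1a at 0.56, Plin2 at 0.81 and Gstp1 at 1.31. Cyp2e1 at -0.57 and Alb at -1.14 stood at 0.73 and 0.16 with spike-in scaling, and Cdkn1a at -0.14 (adjusted p = 0.39) stood at 1.16. The total was 17364 genes, 5740 higher and 11624 lower, with 2572 and 3773 at least 2-fold, and 30 lists, 16 higher and 14 lower. Among the higher lists, endothelial markers (median 0.15) and apoptosis genes (median 0.0029) passed narrowly, each at camera adjusted p = 0.046. Both calls were lost without replicate 1 or 5 of the CDAA diet or replicate 4 or 5 of the normal diet. Without replicate 3 of the normal diet the endothelial call was lost too, and without replicate 2 the apoptosis call. With spike-in scaling 18742 genes were higher and 1186 lower, and 7526 turned from lower to higher. All 5 CDAA arrays lay beyond the normal-diet arrays for 39 of 39 called values of named genes checked at 4 weeks, and 62.1% of all genes did not overlap.

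At 9 weeks scar tissue, bile duct, oncofetal and growth genes stood far above the normal diet. Col1a1 had a log2 fold change of 4.66 (SE 0.17, adjusted p = 6.2e-23), Loxl1 of 4.49, Timp1 of 3.44 and Mmp2 of 3.00, and 34 of 39 matrix genes were higher and 3 lower, Fn1 among these at -1.07 (0.50 with spike-in scaling). The matrix median was 2.24, or 2.21 with bounds (adjusted p = 2.1e-17, and 0.020 with an estimated correlation). Cholangiocyte markers had 17 of 20 higher (median 2.60, or 2.30 with bounds, adjusted p = 2.3e-09, and 0.015 with an estimated correlation), with Cftr at 5.00, Sox4 at 2.87, Krt19 at 2.83 and Epcam at 2.12. Recruited macrophage markers had 15 of 19 higher (median 2.73, or 2.47 with bounds, adjusted p = 2.3e-09, and 0.015 with an estimated correlation), with Trem2 at least 245-fold higher, Clec7a at 4.35, Gpnmb at 4.15 and Cx3cr1 at -2.43. Cytoskeleton genes had 23 of 26 higher (median 2.01, adjusted p = 4.8e-14, and 0.015 with an estimated correlation), with Anxa5 at 3.81 and Anxa2 at 3.57. Mast cell markers had 5 of 9 higher (median 1.70, or 0.86 with bounds, adjusted p = 0.0078, and 0.047 with an estimated correlation), with Hdc at 2.05 and Mcpt1, a mast cell protease, at least 3.76-fold higher (-0.029 and not called with normexp). These are the 5 lists that held with the estimated correlation.

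Further lists were higher at 9 weeks with the preset correlation. Preneoplasia and oncofetal markers had 11 of 15 higher and 0 lower (median 2.82), with Cd44 at 4.34 and Gstp1 at 3.12 (SE 0.37, adjusted p = 1.9e-09), or 2.41 without replicate 4 of the CDAA diet, which stood apart. Among genes above background in both groups H19 had the largest increase at 7.90, then Phgdh at 6.78, Abcb1b at 6.16, Gpx2 at 5.63 and Gstm3 at 5.56, with Fgf21 at 5.12. Cell cycle genes had 36 of 38 higher (median 2.70), with Mki67 at 3.92 and Mcm3 at 2.61. Aurka, a mitotic kinase, was at -1.37, but its other probe was called the opposite way, the mean of both was 0.35 and spike-in scaling gave 0.19. Stellate cell markers had 19 of 27 higher (median 1.05), with Cygb at 3.11, Vim at 2.47, Des at 2.25 and Acta2 at 1.16 (SE 0.12). Chemokines had 23 of 34 higher (median 1.07), with Cx3cl1 at 3.86, Ccl2 at 4.66 and Cxcl12 against the list at -2.75. B cell markers had 6 of 9 (median 0.83, or 0.43 with bounds), with Blnk at least 15.5-fold higher. Pan-macrophage markers had 20 of 22 (median 1.07), Cd68 at 1.22. Medians were 1.38 for antigen presentation (10 of 13), 1.23 for neutrophils (8 of 9, or 1.05 with bounds), 0.61 for T cells (13 of 22, or 0.46 with bounds), 0.40 for p53 targets (12 of 21), 0.40 for apoptosis (12 of 23, with 9 lower) and 0.09 for endothelial markers (9 of 21 higher and 7 lower). The endothelial call was lost without replicate 1 of the normal diet (0.0083, adjusted p = 0.075) or replicate 3 (0.047, adjusted p = 0.057). Adjusted p of these 12 lists ran from 1.3e-17 to 0.042, and from 0.051 to 0.49 with an estimated correlation. Cdkn1a was at 0.11 (adjusted p = 0.48), and at 1.68 with spike-in scaling.

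Most lower lists at 9 weeks were of hepatocyte function, with clock genes and red blood cell markers beside them. Male-biased genes had 18 of 20 lower (median -2.15, spike-in -0.58), with Cyp2c11 at -5.01 and Cyp2a2 at -4.09. Urea cycle and amino acid genes had 28 of 29 (median -1.90, spike-in -0.34), with Kynu and Cdo1 at -2.97 each. Choline and methionine genes had 20 of 25 (median -1.75, spike-in -0.19), with Gnmt at -4.23, Bhmt at -2.63, Ahcy at -2.26 and Mat2a at 2.22. P450 enzymes had 35 of 38 (median -1.63, spike-in -0.06), with Cyp2c7 at -6.89, Cyp3a9 at -6.72, Cyp2d4 at -2.48 and Cyp2e1 at -0.73 (0.84 with spike-in scaling and 0.32 with quantile normalization). Lhx8 at -6.02 and Kcnn2 at -5.92 were next among the largest decreases. Lipogenesis had 19 of 21 lower (median -1.62, spike-in -0.06), with Fasn at -3.29 (SE 0.26, spike-in -1.73), Scd at -2.47 and Dgat2 at -2.38. Hepatocyte secretory genes had 29 of 30 lower (median -1.58, spike-in -0.02), with Fetub at -2.84 and Alb at -1.33 (0.23 with spike-in scaling and 0.14 with quantile normalization). Lipoprotein genes had 20 of 24 lower (median -1.53, spike-in 0.03), with Apoa4 at -3.44 and Pltp at 1.02. Bile acid genes had 17 of 22 lower and 5 higher (median -1.35, spike-in 0.22), with Slc27a5 at -3.21, Baat at -2.44, Abcc3 at least 3.38-fold higher (0.11 and not called with normexp) and Cyp7a1 at -1.07 (SE 0.47, adjusted p = 0.036, spike-in 0.50). That call on Cyp7a1 was lost without any 1 of 5 arrays. Acute-phase proteins had 16 of 21 lower (median -1.34, spike-in 0.23), with Crp at -3.13 and A2m at 3.37. Their camera direction turned with quantile normalization (median -0.14) and in the deposited table (-0.25), neither of which called the list. Oxidative phosphorylation had 45 of 46 lower (median -1.12, spike-in 0.44), with Ndufa6 at -1.35 (0.21). Clock genes had 12 of 14 (median -1.06, spike-in 0.50, Nr1d1 at -2.77), cholesterol synthesis 20 of 25 (median -0.83, spike-in 0.74, Ebp at -2.23, Sqle at 0.59) and red blood cell markers 7 of 9 (median -2.09, spike-in -0.52, Slc4a1 at -3.39, Hbb-b1 at -2.09). The red blood cell call was lost without replicate 3 or 5 of the normal diet (-2.04 and -2.02, adjusted p = 0.052 for both). Adjusted p of these 13 lists was 8.5e-12 to 0.041, and 0.098 to 0.49 with an estimated correlation. Pemt was at -1.40, or 0.17 with spike-in scaling.

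Lists that did not pass at 9 weeks were gluconeogenesis (median -1.27, 11 of 17 lower, adjusted p = 0.076), fatty acid oxidation (median -0.69, 24 of 32 lower and 5 higher, adjusted p = 0.086, Cpt1a at 0.14), lipid droplets (median -0.88, adjusted p = 0.21, Plin2 at 0.47 with SE 0.13), NRF2 targets (median -0.40 and mean 0.34), amino acid response (median -0.46 and mean 0.57), lysosome (median -0.30), interferon-stimulated genes (median -0.10 and mean 0.07), Kupffer cells (median -0.01 and mean -0.51), glycolysis (median 0.12), pancreas (median -0.06) and adipose and muscle (median -0.14). With spike-in scaling the medians of these 11 lists were all above 0, from 0.30 to 1.68. The count was 18316 genes, 5873 higher and 12443 lower, with 3332 and 4863 at least 2-fold. With spike-in scaling 19532 were higher and 1158 lower, and 8951 were lower on the first scale and higher on the second. The 5 values of each diet did not overlap for 67.3% of genes. Of 87 called values of named genes checked at 9 weeks, 85 had all 5 CDAA arrays beyond all normal-diet arrays, the exceptions being Cyp7a1 with 2 and Sqle with 1.

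**Figure D2:**
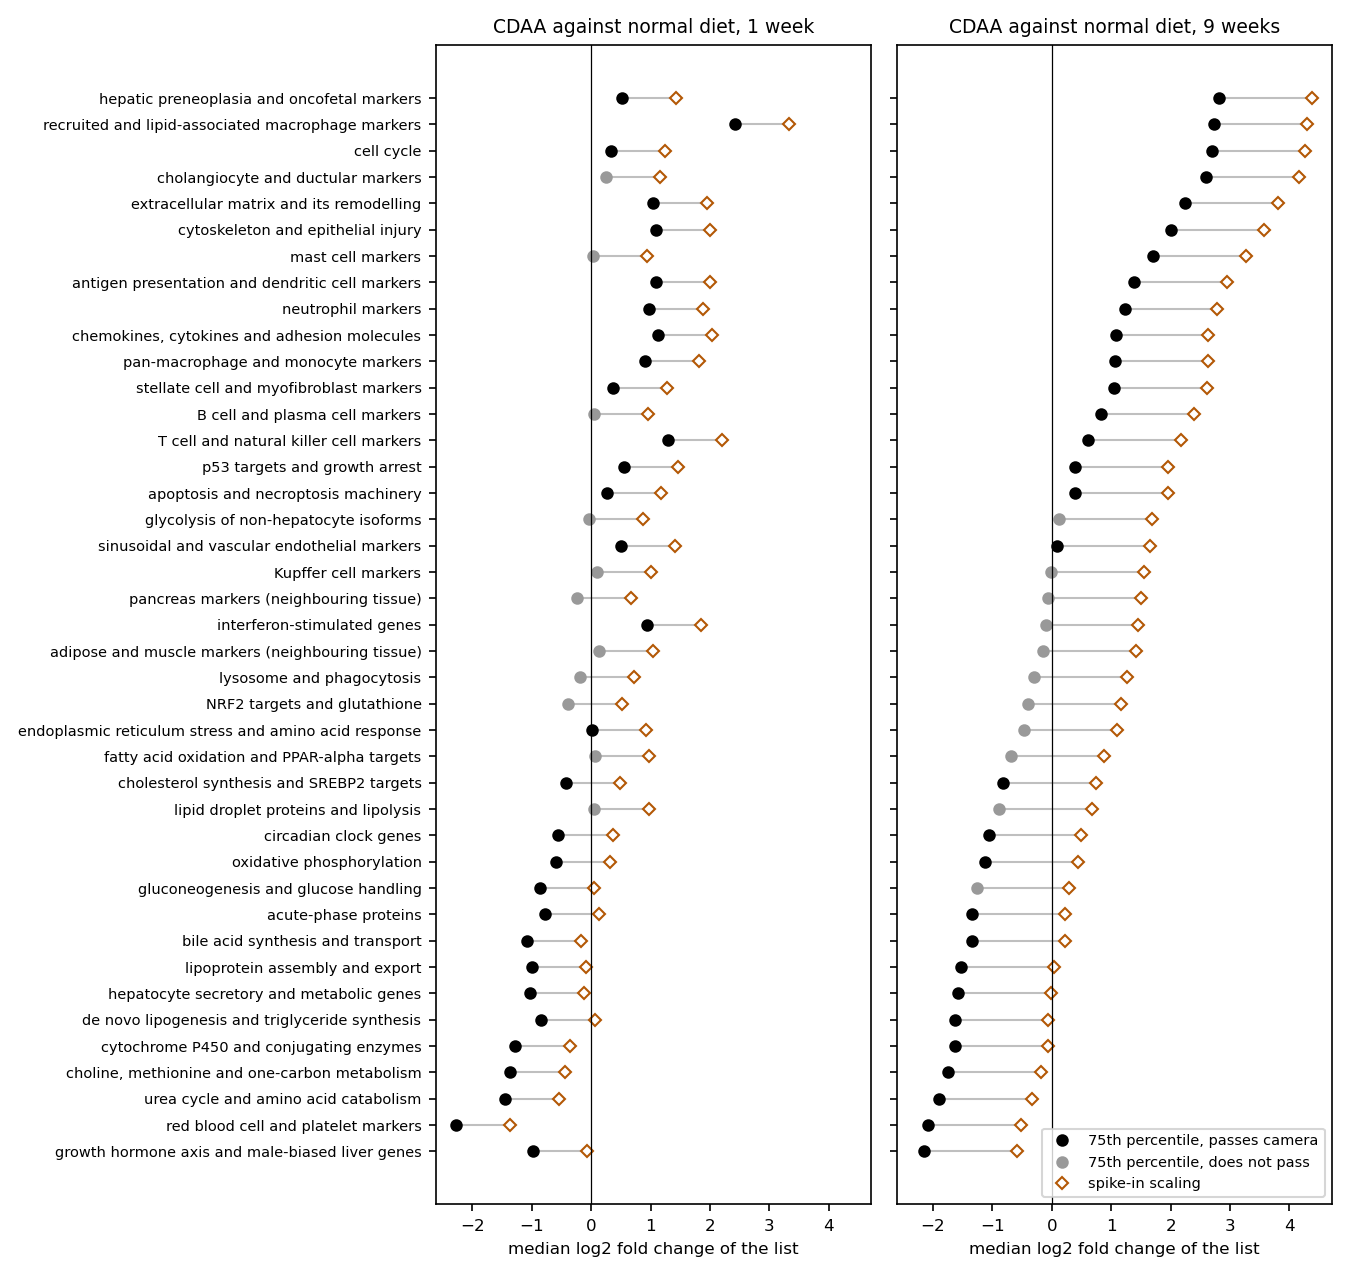
Each row is 1 of the 41 gene lists and the horizontal axis is its median log2 fold change, CDAA against normal diet, at 1 week (left) and 9 weeks (right), with filled circles relative to the 75th percentile (black where camera passed) and open diamonds relative to the spike-in probes. Matrix genes move from 1.04 to 2.24 and hepatocyte secretory genes from -1.03 to -1.58 on the first scale, the latter lying at -0.12 and -0.02 with spike-in scaling.

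**Figure D3:**
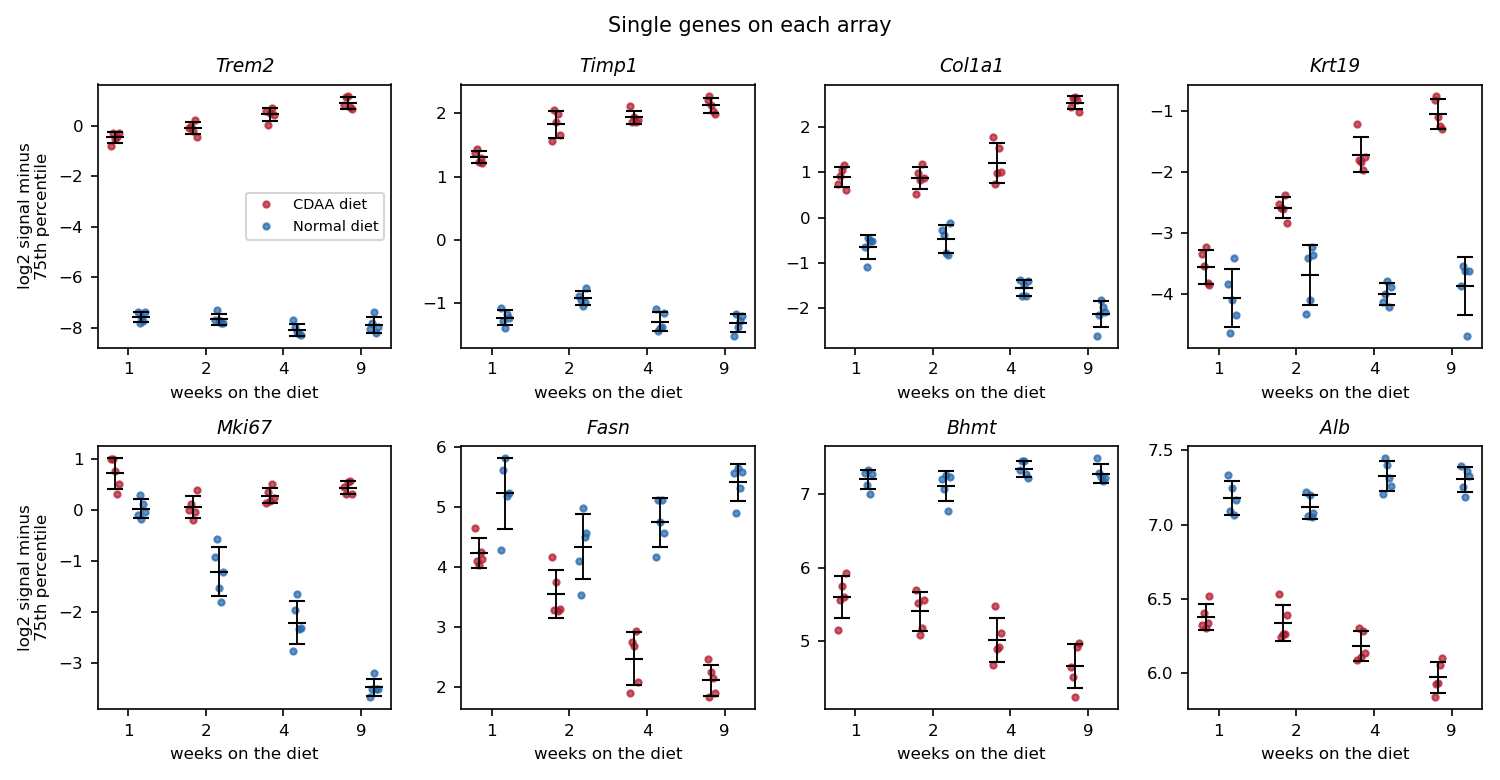
Points are single arrays, log2 signal minus the 75th percentile of the array against weeks on the diet, with mean and SD of 5 arrays for 8 of the indicator genes. Trem2 lies between -8.30 and -7.31 on normal-diet arrays, where it is not well above background, and Mki67 falls with time on the normal diet, so that its log2 fold change goes from 0.69 to 3.92.

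The diet effect had the same direction at all 4 weeks for 11922 genes, 3643 higher and 8279 lower. If calls at the 4 weeks were independent, 86.4 higher and 1205 lower would be shared. With spike-in scaling 15945 were higher and 644 lower throughout. Log2 fold changes of any 2 of the weeks correlated across genes at r = 0.816 for weeks 1 and 9 and up to 0.933 for weeks 4 and 9, with genes not being independent replicates. Directions opposed each other between called weeks for 726 genes, and 1944 were called at no week.

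The difference of the diet effect between 9 weeks and 1 week combines change with time on the CDAA diet and change with time on the normal diet. Sult2a2, a sulfotransferase, had the largest increase of the diet effect at 9.23 on the log2 scale (SE 0.82, adjusted p = 6.8e-11, and 8.5 without replicate 1 of the normal diet at 1 week), then Bex1 at 6.38, Gsta3 at 6.19 and Bex4 at 4.67. Aox3 at -6.69, Dhrs7l1 at -5.82 and Lhx8 at -4.97 had the largest decreases. Sult2a2 and Aox3 were well above background on 1 of 5 arrays of 1 group, and Bex1 and Bex4 on 2 or 3, so their sizes rest in part on dim values. Trem2 and Ccl2 are given no difference here, since at 1 week they were well above background on 0 normal-diet arrays. Of the lists, cholangiocyte markers (17 of 20 members with a larger log2 difference and 1 with a smaller one, median 2.35, camera adjusted p = 1.7e-17) and cell cycle genes (36 of 38, median 2.20, adjusted p = 4.7e-33) had the highest medians. Their order is not settled: at 9 weeks 6 cholangiocyte members have only a bound, and with bounds that list goes from 0.25 at 1 week to 2.30 and cell cycle from 0.33 to 2.70. Cell cycle genes fell on the normal diet (median -2.52) and did not rise on the CDAA diet (median -0.28). Next were preneoplasia markers with 11 of 15 (median 1.3), matrix genes with 27 of 39 (median 1.17), cytoskeleton with 15 of 26 (median 0.73) and stellate cells with 16 of 27 (median 0.56). These 6 lists held with the estimated correlation at adjusted p of 0.00078 to 0.028. Mast cell (median 1.22), pan-macrophage (median 0.11) and recruited macrophage markers (median 0.13) also passed with an upward shift, at adjusted p of 0.017 to 0.034, and 0.11 to 0.61 with an estimated correlation. Without any 1 of 3 arrays the pan-macrophage call was lost. The diet effect was larger by 3.12 for Col1a1, 3.23 for Mki67, 2.39 for Gstp1 (1.68 without replicate 4 of the CDAA diet at 9 weeks), 2.33 for Krt19, 0.90 for Timp1 and 0.78 for Acta2. Cyp7a1 changed by 2.86, Cdkn1a by 0.53, a call lost without any 1 of 8 arrays, and Cyp2e1 by 0.37, a call lost without replicate 3 of the normal diet at 9 weeks (0.31, adjusted p = 0.056).

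Downward differences covered 11 lists with medians from -1.01 for male-biased genes and -0.78 for interferon-stimulated genes, of which 18 of 28 fell and 0 rose, to -0.41 for choline and methionine genes. The others were lipid droplets (-0.67), fatty acid oxidation (-0.65), lipogenesis (-0.63), oxidative phosphorylation (-0.56), lipoproteins (-0.55), acute-phase proteins (-0.55), hepatocyte secretory genes (-0.54) and urea cycle (-0.46). Adjusted p was 7.9e-15 to 0.026, and 0.21 to 0.59 with an estimated correlation. With spike-in scaling the medians were -0.35 for male-biased, -0.13 for interferon-stimulated and -0.02 for lipid droplet genes, and 0.00 to 0.24 for the other 8. Fasn changed by -2.30, Scd by -1.27, Bhmt by -1.02, Plin2 by -0.62 (0.03 with spike-in scaling), Alb by -0.53 (0.13) and Pemt by -0.48 (0.18). Adjusted p of these genes and of those with a larger effect was 0.034 or less. Fgf21 at -0.76 (adjusted p = 0.25), Cpt1a at -0.46 and Cd68 at 0.14 were not called. Counts were 10487 genes, 2803 up and 7684 down, with 1487 and 1073 at least 2-fold, and with spike-in scaling 10771 up and 601 down. Of 13363 genes called in 1 direction at both weeks, the effect was larger at 9 weeks for 6414, smaller for 328 and not called different for 6621. These counts are relative to the 75th percentile and were not made with spike-in scaling, which adds 0.65 to every difference. Of the 7684 downward differences 601 were called downward on both scales and 932 were called upward with spike-in scaling. The number with a larger effect therefore depends on the scale. The F test called 11451 genes with a diet effect that differed among the 4 weeks.

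**Figure D4:**
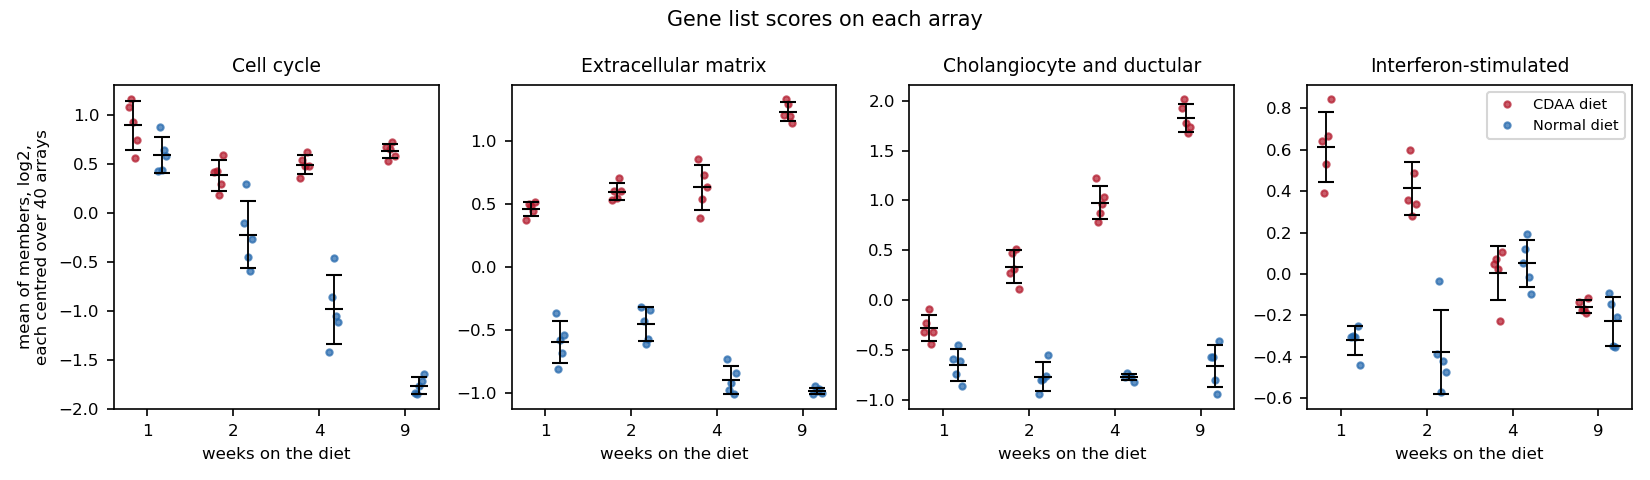
The mean score of 4 lists on each array, log2 and centred over the 40 arrays, is plotted against weeks on the diet with the mean and SD of 5 arrays. Cell cycle scores fall on the normal diet (list median -2.52 from 1 to 9 weeks) far more than on the CDAA diet (-0.28), matrix and cholangiocyte scores rise on the CDAA diet, and the interferon-stimulated difference of 1 week is no longer called at 4 and 9 weeks.

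On the normal diet, 9 weeks were set against 1 week. In this comparison time and slide lie together for 4 of 5 arrays of a group. Scan day lies with time as well: all 9-week arrays were scanned on 1 day, and 1-week arrays on another apart from replicate 5. Cell cycle genes fell: 37 of 38 were lower and 0 higher (median -2.52, and -2.99 with spike-in scaling, camera adjusted p = 2.5e-57, and 0.0041 with an estimated correlation). Ccnb1, a mitotic cyclin, was at -3.82 (SE 0.25, adjusted p = 2.2e-14), Knstrn, of the mitotic spindle, at -3.80 and Cenpw, of the centromere, at -3.80. Gsta3 at -4.31 and Prlr, the prolactin receptor, at -3.83 (SE 0.90) also fell, and Dact1 at 3.84, Cish at 3.44 and Cdh17 at 3.11 rose. For each of these 8 genes the 5 arrays of 9 weeks lay beyond the 5 of 1 week, which was a condition for naming them. With the slide as a block Dact1 (2.06), Cish (2.32) and Prlr (-2.84) were no longer called. Prlr was at -2.99 without replicate 4 of 9 weeks. Matrix genes (19 of 39 lower, median -0.33), red blood cell markers (6 of 9, median -0.76) and cytoskeleton genes (8 of 26 lower and 4 higher, median -0.10) were lower, and acute-phase proteins (13 of 21, median 0.33), hepatocyte genes (12 of 30, median 0.22), oxidative phosphorylation (20 of 46, median 0.14) and fatty acid oxidation (10 of 32, median 0.15) were higher. Adjusted p of these 7 was 6.4e-08 to 0.045, and 0.63 to 0.97 with an estimated correlation. With spike-in scaling the 4 higher lists had medians of -0.14 to -0.34. The called genes numbered 7906, 5092 higher and 2814 lower, with 428 and 701 at least 2-fold, and with spike-in scaling 432 higher and 14981 lower. Arrays of 1 and 9 weeks lay on different slides apart from 1 array of each group, and with the slide as a block 2825 genes were called. On the CDAA diet itself 11549 genes differed between 9 weeks and 1 week, 3117 higher and 8432 lower (3464 and 2406 with spike-in scaling), and 24 lists, 11 higher and 13 lower, with cholangiocyte (median 2.37) and mast cell markers (median 1.32) highest and cell cycle genes not passing (median -0.28, adjusted p = 0.59).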

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

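Chosen only after the results were seen were the tests of slide position, of fewer hepatocytes, of the scale for hepatocyte genes, of cell cycle genes within each diet, and the splits of the arrays at every comparison.

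Single arrays stood apart from the other 4 of their group in 15 of 200 groups of values tested, where chance gives 10 at 1 in 20. In array measures these were a 75th percentile of 1921 in Normal_2w replicate 2 (next 1739), 49.2% of probes above background in CDAA_2w replicate 4 (next 57.7%) and 52.8% in Normal_4w replicate 5 (next 49.3%). Negative control signal was 43.6 in CDAA_1w replicate 5, 42.4 in Normal_1w replicate 5 and 43.3 in Normal_2w replicate 5. All 3 were on the slide that holds every group, which was scanned on another day than the other 4 arrays of these groups. In genes they were, in log2 signal relative to the 75th percentile, Cyp7a1 at -2.68 in CDAA_2w replicate 2 and -4.07 in CDAA_4w replicate 4, Acta2 at -3.28 in CDAA_1w replicate 2, Trem2 at -7.31 in Normal_2w replicate 2, where it is not well above background, Krt19 at -1.22 in CDAA_4w replicate 1 and -4.69 in Normal_9w replicate 4, Gstp1 at 4.70 in CDAA_9w replicate 4 (next 1.76), and Cyp2e1 at 5.91 in CDAA_2w replicate 1 and 5.42 in CDAA_9w replicate 4.

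The diet effect was called different between 9 weeks and 1 week, by a test of that difference, for 24 named genes. Trem2 and Ccl2 are among these, but their calls rest on dim values and are left open below. On the log2 scale the difference was -2.30 for Fasn, -1.27 for Scd, -0.62 for Plin2, 2.86 for Cyp7a1, -0.48 for Pemt, -1.02 for Bhmt, 3.12 for Col1a1, 0.78 for Acta2, 0.90 for Timp1, 1.68 for Trem2, -1.46 for Ccl2, 2.33 for Krt19, 3.23 for Mki67, 0.53 for Cdkn1a, 2.39 for Gstp1, 0.37 for Cyp2e1 and -0.53 for Alb. It was 9.23 for Sult2a2, 6.38 for Bex1, 6.19 for Gsta3, 4.67 for Bex4, -6.69 for Aox3, -5.82 for Dhrs7l1 and -4.97 for Lhx8. The sizes for Trem2, Ccl2, Sult2a2, Bex1, Bex4 and Aox3 are not measured well, because each was well above background on 3 arrays or fewer of at least 1 group. Trem2 and Ccl2 were well above background on no normal-diet array at 1 week, so whether their diet effect differed stays open. Without CDAA_9w replicate 4 the difference of Gstp1 was 1.68. It also differed for 20 lists, 6 of which hold with the estimated correlation, with medians of -0.63 for lipogenesis, -0.65 for fatty acid oxidation, -0.67 for lipid droplets, -0.55 for lipoproteins, -0.41 for choline and methionine, -0.54 for hepatocyte secretory genes, -0.46 for urea cycle, -0.56 for oxidative phosphorylation, 1.17 for matrix, 0.56 for stellate cells, 0.11 for pan-macrophage, 0.13 for recruited macrophage, 1.22 for mast cell, 2.35 for cholangiocyte and 1.3 for preneoplasia markers, -0.55 for acute-phase proteins, -0.78 for interferon-stimulated genes, 2.20 for cell cycle, 0.73 for cytoskeleton and -1.01 for male-biased genes.

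Other splits of the same arrays test whether chance alone gives as much, with 100 splits drawn for each result. For genes called between diets chance can be excluded at each week: 1 of 100 splits, the real one, gave as many, with 15429, 16143, 17364 and 18316 genes at weeks 1, 2, 4 and 9 against at most 10412, 11858, 13198 and 14573 in another split. Splits that exchange few arrays still carry much of the diet effect, which is why their counts are high. For 30 lists called at each week, 2, 7, 3 and 4 of the splits gave as many, with at most 31, 32, 30 and 30 in another split. That is fewer than 5 of 100 at weeks 1, 4 and 9 and not at 2 weeks. Since other splits reached 30 or more at every week, the number of lists hardly separates the diets from mixed groups. No conclusion on chance is drawn from it. For the 11451 genes of the F test 1 split gave as many, with at most 9927 in another. These splits shuffle diets within weeks, so they test for no diet effect and not for an equal effect at all 4 weeks. No conclusion on chance is drawn for the F test. Chance can be excluded for the 11922 genes shared by all 4 weeks (1 split, at most 0 in another) and the 7906 genes that differed with time on the normal diet (1 split, at most 2907). In the last case the splits do not separate time from slide or scan day. Of each week 4 of 5 arrays have a slide of their own, and with the slide as a block 2825 genes are called. For the 10487 genes whose diet effect differed between weeks, diets shuffled within weeks gave as many in 6 splits, with up to 16340, and for the 20 lists in 57 splits, with up to 31, so chance was not excluded. Those splits contain the diet effect itself at 1 week or 9 weeks, which is a structure of the arrays. With weeks exchanged within each diet, 1 split gave as many genes (at most 8131 in another). These splits test for no change with time on either diet and not for an equal diet effect at both weeks. No conclusion on chance is therefore drawn for these genes. As many lists came from 18 such splits (at most 26), and chance cannot be excluded for the number of lists.

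CDAA arrays are brighter relative to the spike-in probes. Position on the slide, hybridisation and scanning would raise the spike-in probes as well, and their highest weekly difference, CDAA minus normal diet, was -0.023, which argues against these as the cause. Less labelled RNA of every kind on the normal-diet arrays cannot be told apart from a change in composition. Summed signal differed by 0.578 of the difference in the 75th percentile at the lowest week (0.639, 0.606 and 0.582 at the others), less than an equal loss gives, but compression of bright signal would lower the ratio and keeps this open. A few abundant transcripts holding more of the signal on normal-diet arrays is open too: the 100 brightest genes held 3.48 points more of the signal on the normal diet at 1 week, the lowest, and 5.40 at 4 weeks, the highest (exact permutation p = 0.00794 at each). A larger amount of other RNA in CDAA liver may contribute, which was not tested.

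Hepatocyte genes are lower on the CDAA diet at 9 weeks, with a list median of -1.58. Fewer hepatocytes would raise the markers of all other cell types alike, whereas the medians of 4 lists were -0.01 for Kupffer cells, 0.09 for endothelium, 2.73 for recruited macrophages and 2.60 for cholangiocytes, a range of 2.74. The score of recruited macrophages minus that of Kupffer cells was 2.03 ± 0.13 on the CDAA diet and -1.48 ± 0.13 on the normal diet (SD, n = 5, exact permutation p = 0.00794). These macrophage lists were compared after their values were known, so the p value adds no weight. Kupffer markers also part, with Marco at -2.51, C6 at -2.96 and Folr2 at 1.26. The medians argue only against a loss of hepatocytes with all other cell types raised alike. They do not test whether hepatocytes were fewer, and growth of the cell types that rose stays open. The choice of scale may account for the list as a whole, since its median is -0.016 with spike-in scaling. At 9 weeks 482 genes are at least 2-fold lower on both scales, a number that follows from the size of the shift and does not test the scale.

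Cell cycle genes have a larger diet effect at 9 weeks than at 1 week. Higher expression at 9 weeks on the CDAA diet itself is argued against by a median of -0.28 between those weeks. A decline on the normal diet has the values it needs, with a median of -2.52, and it may reflect the age of the rats, which the design does not separate from other changes with time. On the slide that holds every group the normal-diet difference was -2.31 with 38 of 38 members lower, and -0.14 on the CDAA diet with 26 of 38 lower. This goes against slides that differ between weeks as the cause, but with little weight. Each group has 1 array there, so the difference has no measured spread.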

How the results depend on the processing

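Scaling to spike-in probes, median centring and leaving out slide 2 were chosen after seeing the data, and signal over background limits the genes that are dim on 1 diet.

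With 1 array left out in turn, genes called were 14855 to 15183 at 1 week, 15558 to 15897 at 2, 16885 to 17161 at 4 and 17917 to 18171 at 9 weeks, 9935 to 10562 for the difference between weeks, 10797 to 11563 in the F test, 11650 to 11965 at all 4 weeks and 6859 to 7711 with time on the normal diet. Lists called were 29 to 31 at 1 week, 28 to 30 at each other week and 19 to 21 for the difference. Of 3160 values of named genes 34 lost their call and 0 changed direction, and of 2460 values of lists 30 lost and 8 gained a call. Lost calls at 9 weeks include Cyp7a1 (-1.07 to -0.79 without replicates 2, 3 or 5 of the CDAA or 1 or 2 of the normal diet). At 1 week they include Krt19 (0.36 to 0.50 without replicates 1, 2 or 3 of the CDAA or 2, 3 or 5 of the normal diet).

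Arrays of both diets with 1 replicate number share a slide and a column on it in 20 of 20 pairs. Their deviations from the group means correlated at r = -0.040 to 0.19 (median 0.058), over 0.1 in 4 pairs. Not every array correlated best with its own number: 12 of 20 CDAA and 13 of 20 normal-diet arrays did, where chance gives 4. The labels state no pairing, and paired rats and a shared place on the slide cannot be told apart. With the replicate number as a block 15588, 16307, 17496 and 18475 genes and 30, 29, 30 and 30 lists were called at weeks 1, 2, 4 and 9. This block sets 1 offset for each replicate number across all weeks. An offset for each of the 20 pairs was not fitted, so these counts do not test the pairing.

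Some counts moved more than 1.5 times. With normexp correction genes called higher fell from 5510, 5752, 5740 and 5873 to 3420, 3648, 3295 and 3321 at weeks 1, 2, 4 and 9 and from 3643 to 2118 at all 4 weeks, while 15198 to 17308 were lower. Genes at least 2-fold higher fell from 1960 to 552 at 1 week and from 3332 to 1140 at 9 weeks. Of 205 list results 31 lost and 15 gained a call. The cause was not tested. Without a filter on dim probes 29398 genes were called at 4 weeks and 30677 at 9 weeks, because more were tested. With spike-in scaling 15413 genes differed with time on the normal diet, 432 higher and 14981 lower, and with the slide as a block 2825. A fold of at least 2 left 4128, 4661, 6345 and 8195 genes at weeks 1, 2, 4 and 9, 2560 for the difference between weeks, 1129 with time on the normal diet and 2829 at all 4 weeks, by its stricter construction, and an adjusted p under 0.01 left 5238 with time on the normal diet. With an estimated correlation 2, 2, 4 and 5 lists were called at the 4 weeks and 6 for the difference, and 121 of 205 list results lost their call, since a higher correlation widens the test. Quantile normalization left 13 lists for the difference, and the cause was not tested.

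Directions reversed for 27 of 289 gene results with spike-in scaling, which adds 1 amount to every gene of a comparison. At 1 week these were Cdkn1a 0.49, Alb 0.11, Marco 0.71, Sdf2l1 0.24 and Pdia4 0.70. At 2 weeks they were Fasn 0.27, Pemt 0.18, Cdkn1a 0.47, Cyp2e1 0.38, Alb 0.28 and Cyp2c12 0.27, and at 4 weeks Pemt 0.011, Cdkn1a 1.16, Cyp2e1 0.73, Alb 0.16 and Cyp2c12 1.06. At 9 weeks they were Cyp7a1 0.50, Pemt 0.17, Cyp2e1 0.84, Alb 0.23, Fn1 0.50, Aurka 0.19, Ndufa6 0.21 and Pdia4 0.14, and for the difference between weeks Plin2 0.030, Pemt 0.18 and Alb 0.13. The lysosome list turned to 0.72 at 1 week, 1.26 at 9 weeks and 0.54 for the difference.

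Quantile normalization turned Alb to 0.13, 0.17, 0.12 and 0.14 at weeks 1, 2, 4 and 9 and 0.018 for the difference, and Cyp2e1 to 0.18 at 4 and 0.32 at 9 weeks. The camera direction of acute-phase proteins turned, with medians of 0.00046, 0.066, 0.00057 and -0.14. The deposited table gave 0.10, 0.15, 0.14 and 0.11 for Alb and 0.0060 for its difference, 0.19 and 0.36 for Cyp2e1, medians of -0.0070, -0.11, -0.092 and -0.25 for acute-phase proteins, and 0.053 for lysosome genes at 9 weeks and -0.0089 for their difference. Normexp correction gave -0.022 for Acta2 at 2 weeks, -0.029 for Mcpt1 at 9 weeks and a median of -0.30 for fatty acid oxidation at 4 weeks, whose camera direction turned. The mean of both probes gave 0.35 for Aurka at 9 weeks, where its probes disagree. Apart from Aurka the cause was not tested. Quantile normalization and the deposited table turned the same named genes and may not be independent alternatives. The highest value of the table recurs between columns, as quantile normalization would give. It was 18.706 in CDAA_1w replicates 1 and 2 and in Normal_1w replicate 5, for example. Among the other alternatives (median centring, 2 filters, variance, array weights, groups compared, blocks and leaving out slide 2) 0 named genes and 0 lists changed direction, and without slide 2 the diet called 14786 to 17837 genes at a week, with 5 gene and 7 list results losing their call.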

Other observations

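The test of both parts of the amino acid response list was chosen only after its values were seen, as were the genes named below.

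At each week the amino acid response members of the list had a higher median log2 fold change than the chaperones. The direction of the chaperones depends on the scale. Relative to the 75th percentile 7 of 16 chaperones were lower and 2 higher at 1 week (median -0.15), and 16 of 16 were lower at 9 weeks (median -0.93). With spike-in scaling their median was above 0 at each week (0.76, 0.46, 0.43 and 0.64). Phgdh, Psat1 and Asns, of serine and asparagine synthesis, had log2 fold changes of 3.79, 2.41 and 3.48 at 1 week and 6.78, 3.92 and 4.37 at 9 weeks, and Trib3, a stress regulator, 3.43 and 3.51. Edem1 and Sdf2l1, of protein folding, were at -1.52 and -0.67 (0.24 with spike-in scaling) at 1 week and -1.94 and -1.67 at 9 weeks, and Pdia4 at -0.21 and -1.42 (0.70 and 0.14 with spike-in scaling). The 1-week call on Pdia4 was lost without any 1 of 3 arrays (-0.21 to -0.18). The medians of 16 amino acid response members and 16 chaperone members differed by 1.68 at 1 week, the smallest of the 4 weeks (permutation p = 0.00014, adjusted p = 0.00014), with 13 and 2 members called higher. The parts of the list may answer differently to the diet, with little weight, since the parts were drawn after their values were known and members are not independent.

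Other lists hold genes that part. Acot1 and Vnn1, targets of PPAR-alpha, were at least 112-fold higher and at 3.94 at 1 week, while the fatty acid oxidation list had a median of 0.06. Among NRF2 targets and antioxidant genes Gpx2 was at 5.63 and Slc7a11 at least 8.84-fold higher at 9 weeks, and Cat at -2.57 and Gpx1 at -1.95. Among Kupffer cell markers Marco was at -2.51 and C6 at -2.96 at 9 weeks and Folr2 at 1.26.

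Male-biased liver genes were lower, and a turn from a male to a female pattern could lower them. It would raise A1bg and Cyp2c12, which are female-biased in rats. A week counted where a gene was called higher by at least 1 and also stood at 1 or more with spike-in scaling. The gene with fewer such weeks had 0 of 4. A1bg was lower at each week on both scales, which argues against a full turn, though by 1 gene only. Cyp2c12 depends on the scale: with spike-in scaling it was called higher by at least 1 at weeks 1, 4 and 9 (adjusted p = 0.00081, 0.0033 and 2.2e-06). Cyp2c12 was at 0.34, -0.79, -0.23 and 0.33 at weeks 1, 2, 4 and 9 (1.3, 0.27, 1.06 and 1.89 with spike-in scaling). The 2-week call was lost without CDAA_2w replicate 1 (-0.59, adjusted p = 0.093) or Normal_2w replicate 3 (-0.51, adjusted p = 0.13). A1bg was at least 17.5-fold lower at 1 week and 8.63-fold lower at 4 weeks. At weeks 2 and 9 it was well above background on 5 normal-diet arrays and 1 CDAA array, too few for a fold. The sex of the rats is not given.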
